A study of Mus musculus with 12 samples.

How the data were processed

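Chromatin accessibility was measured by ATAC-seq in mouse CD4+ T cells (C57BL/6, spleen). Sorted naive CD4+ cells were stimulated with plate-bound anti-CD3 and anti-CD28 antibodies (1 µg/ml each). Non-pathogenic Th17 cells (Th17n) received 25 ng/ml IL-6 and 2 ng/ml TGF-beta1. Induced regulatory T cells (iTreg) received 2 ng/ml TGF-beta1. Cultures ran for 68 hours with 100 µM DFMO (difluoromethylornithine, an inhibitor of the polyamine enzyme ornithine decarboxylase) or vehicle. Live cells were sorted, frozen, thawed and tagmented with Tn5 for 30 min. After 5 pre-amplification cycles and a final amplification, libraries were sequenced as 37 bp read pairs on an Illumina NextSeq instrument. The labels give each library an animal number, 1 to 3 in each of the 4 groups, which gave 12 libraries.

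The deposited values are raw counts, 1 whole number per peak and library, for 48443 peaks of the mouse genome build mm10, and carry no scaling. Trimmomatic, FastQC, Bowtie2 and MACS2 are listed per the submitters' processing notes; their versions, settings and roles are not given in the sources used here. The sources do not state whether peak starts count from 0 or 1, and starts are printed as the table gives them. Total counts per library ran from 1020937 to 6496550, a ratio of 6.36. Every count column belonged to 1 of the 12 libraries, and 0 were left unused. Peaks were a median of 480 bp wide (137 to 3913 bp).

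Each peak was assigned to the nearest protein-coding gene model of an annotation of the same build (GRCm38.p6) within 100 kb; 46093 peaks were assigned, to 14550 of 21900 genes. The annotation used here gives no strand, so the distance is to the gene model and not to the transcription start site named in the plan. A peak within 1 kb of either end of its gene model was placed at a gene end (12193 peaks). The others lay inside a gene model (20661 peaks) or outside (13239 peaks). Another 2350 peaks had no gene within 100 kb. Assignment by distance does not show which gene a region controls.

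Counts were tested in R 4.3.3 with edgeR 4.0.16: filterByExpr by group (minimum count 10), TMM factors, trended dispersion, glmQLFit and glmQLFTest. All 12 libraries entered 1 model of 4 group means without a block. Benjamini-Hochberg adjusted p had a threshold of 0.05. The filter kept 43726 peaks and left 4717 untested. The contrasts were DFMO against vehicle in Th17n and in iTreg, Th17n against iTreg in vehicle and in DFMO, and the interaction (DFMO effect in Th17n minus that in iTreg). Reported log2 changes are edgeR estimates with a standard error (SE). Accessibility is given as CPM (counts scaled to a TMM-scaled library total of 1e6), as mean ± SD of 3 libraries. Principal components were taken from log2 CPM with a prior count of 2. All p-values rest on 3 animals per group.

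The labels give an animal number for each library, and pairing by it was checked: after removal of group means, 18 pairs of libraries from the same animal correlated between -0.055 and 0.075, and 7 of 12 libraries correlated best with another library of their own animal. Within groups, log2 CPM correlated at 0.883 to 0.960, against at most 0.793 between lineages. The lowest chi-square per degree of freedom between libraries of a group was 2.03, so the spread exceeded counting error.

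For the question of lineage-specific regions, lineage peaks were defined on the Th17n-iTreg difference averaged over both treatments, which shares no chance value with the DFMO effect within a lineage only if the groups are equally precise. They were not, and simulation without a DFMO effect gave slopes of 0.0028 to 0.010 in Th17n and -0.022 to -0.015 in iTreg. The DFMO effect was then regressed on the lineage effect over these peaks. A list from the vehicle libraries alone, which does share libraries, was an alternative. For both lists, slopes were taken from 20 simulated data sets without a DFMO effect. These draw each peak independently, so they show what unequal precision and shared libraries give, and not variation shared by the peaks of a library. The 16 gene lists hold 250 genes, of which 229 had a peak: Th17, Treg, Th1, Th2 and Tfh programmes, naive and memory T cell genes, activation and AP-1, TGF-beta and STAT feedback, polyamine metabolism, chromatin and DNA modifiers, glycolysis, cell cycle, interferon response, and 3 lists of other cell types (cytotoxic T and NK, B and myeloid cells). Lists were tested with camera (limma 3.58.1, preset correlation 0.01, Benjamini-Hochberg over 16 lists per contrast), with an estimated correlation and fry as alternatives. "Adjusted over the list alone" means that only the list's own peaks entered the adjustment.

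Genes were named by rule. The rule takes, per contrast, the 8 higher and 8 lower peaks with the smallest adjusted p that went the same way in all 3 animals, with 1 peak per gene. It adds up to 4 genes per list with the smallest p among peaks past the threshold, or up to 2 where none passed, and a fixed set of genes, shown here for Il17a, Il17f, Il23r, Foxp3, Il2ra, Ikzf2, Tbx21, Ifng, Odc1, Sat1 and Kdm6b. Some genes that the rule names are not reported here. Each fixed gene was tested at the peak nearest a gene end and at its peak of smallest p; the second is given where it passed. Genes given for their number of changed peaks, and small RNA, histone and ribosomal protein genes, fall outside the rule and were chosen after their values were seen. Groups, contrasts, tests, gene lists and the rule were set before the data were examined.

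The test was tried on simulated data, negative binomial counts drawn independently for each peak with the fitted dispersion and the 12 library sizes, with 200 changed peaks per comparison among 43726. In Th17n under DFMO it recovered 2.99% of 1.5-fold, 44.8% of 2-fold and 71.2% of 4-fold changes, with 3 false calls. In iTreg under DFMO the shares were 13.4%, 31.8% and 81.8%, with 1 false call. In the vehicle lineage contrast they were 10.4%, 43.3% and 81.5%, with 6. For the interaction they were 0%, 7.46% and 51.5%, with 0. A simulated 1.4-fold shift of the Treg list was ranked first in each comparison, and in the interaction 1 unshifted list also passed. Calls numbered 95 in the simulation of DFMO in Th17n, against 3841 in the data. With fewer calls the adjusted threshold is stricter, so the recovered shares can understate those in the data.

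Alternatives for every count of changed peaks were DESeq2 1.42.0, RLE factors, library totals alone, no count filter, at least 30 counts in 3 libraries, the animal as a block, only the libraries of the groups compared, autosomes only, a stricter adjusted p of 0.01, and leaving out each library in turn. Lists were also tested with peaks within 1 kb of a gene end and within 20 kb of the gene model. After the data were seen, abundance-trended (loess) offsets, the same with the animal block, and thinning of all libraries to the smallest total were added. Gene classes (tRNA, snRNA, snoRNA, miRNA, rRNA, lncRNA, histone and ribosomal protein genes; peaks within 200 bp of the gene; 32 tests adjusted together) were also added then, each compared with 1000 random lists of matched strength, width and place. Offsets for GC content and the motif content of changed peaks were not run, because no genome sequence was used here. Tables and plots used python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.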

Results

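Accessibility at 48443 regions was counted in 12 ATAC-seq libraries: Th17n with vehicle, Th17n with DFMO, iTreg with vehicle and iTreg with DFMO, 3 animals in each. Total counts were 1020937, 6496550 and 3405449 for Th17n with vehicle (animals 1, 2 and 3) and 3077794, 2311124 and 1535786 for Th17n with DFMO. They were 1955327, 4652271 and 4946527 for iTreg with vehicle and 1703720, 2107652 and 3412225 for iTreg with DFMO. Lineage was the largest source of difference: the first principal component held 56.0% of the variance and placed Th17n vehicle at -140.3 to -129 and all 6 iTreg libraries at 77.9 to 133. Th17n cells with DFMO lay nearer to iTreg on it, at -102 to -84.8. The second component (10.5%) parted all 6 vehicle libraries (29.7 to 84.5) from all 6 DFMO libraries (-77.7 to -25.8). The share of counts at gene ends was 46.4% ± 0.481 (SD, n = 3) in Th17n vehicle, 48.6% ± 0.895 in Th17n with DFMO, 55.3% ± 1.17 in iTreg vehicle and 56.8% ± 1.00 in iTreg with DFMO. The strongest 10% of peaks held 34.9%, 37.3%, 42.1% and 43.8% of counts in the same order.

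**Figure D1:**
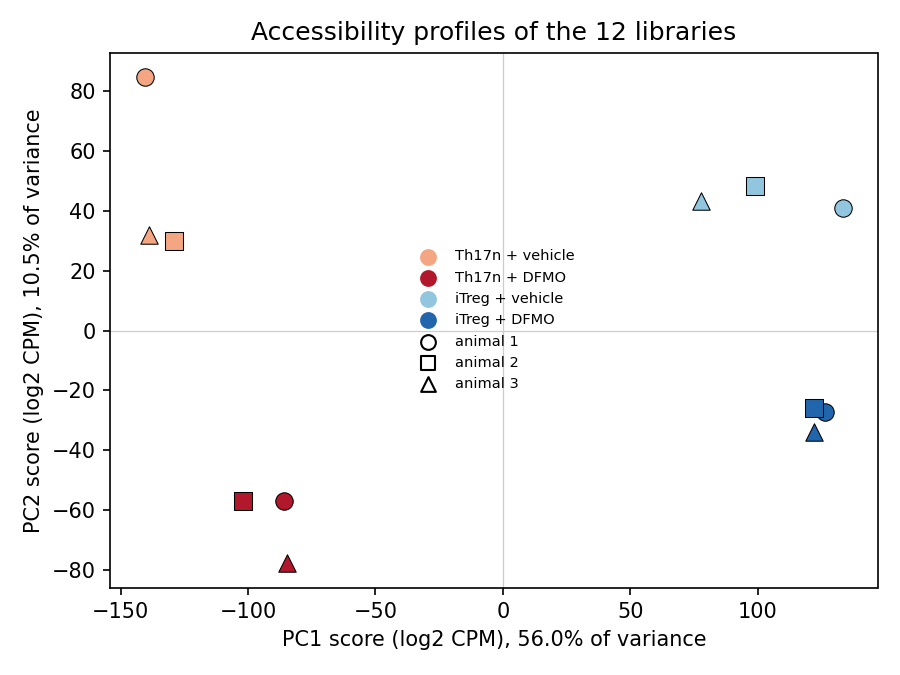
Scores of the 12 libraries on the first 2 principal components of log2 CPM (56.0% and 10.5% of the variance); colour gives the group and symbol the animal. Th17n libraries lie at -140.3 to -84.8 on the first axis and iTreg libraries at 77.9 to 133, and DFMO libraries lie below 0 on the second.

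The first question was which regions of Th17n cells change with DFMO. The Tnfrsf18 gene encodes GITR, a co-stimulatory receptor abundant on regulatory T cells. A peak outside it (mm10, chromosome 4, 156030655 to 156031480) fell from 87.7 ± 6.55 CPM to 22.9 ± 4.5 (SD, n = 3), a log2 change of -1.92 ± 0.19 (SE; adjusted p = 1.5e-09). A peak inside Zmiz1, which encodes a transcriptional coregulator (chromosome 14, 25561693 to 25562744), fell from 71.1 ± 16.2 to 13.9 ± 5.10 CPM (-2.41 ± 0.24, adjusted p = 2.1e-09). The Ctla4 gene encodes the inhibitory receptor CTLA-4; its peak at a gene end (chromosome 1, 60916453 to 60917552) fell from 64.9 ± 5.68 to 18.7 ± 10.0 CPM (-1.70 ± 0.24, adjusted p = 4.6e-06). At a gene end of Rpl3, which encodes a ribosomal protein (chromosome 15, 80075748 to 80077225), accessibility rose from 31.9 ± 2.65 to 98.0 ± 18.5 CPM (1.65 ± 0.17, adjusted p = 9.6e-09). At a gene end of Mrpl58, which encodes a protein of mitochondrial ribosomes (chromosome 11, 115412420 to 115414041), it rose from 94.6 ± 11.8 to 199.6 ± 18 CPM (1.05 ± 0.11, adjusted p = 1.8e-08).

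Among the other strongest gains were peaks at Ctc1 (1.69 ± 0.19, adjusted p = 2.4e-08), Osbp (1.94 ± 0.22, adjusted p = 5.4e-08), Slfn14 (1.47 ± 0.16, adjusted p = 1.3e-08) and Mef2c (1.99 ± 0.24, adjusted p = 1.8e-07). Smaller gains lay at Kif2c (1.28) and Arl4d (1.21). Of the 8 strongest gains, 6 lay at a tRNA or snRNA gene as well as at the protein-coding gene named: tRNA genes at Mrpl58, Ctc1 and Osbp, and snRNA genes at Slfn14, Kif2c and Arl4d. The other strong losses were at Ralgds (-1.57 ± 0.17), Pdp1 (-2.04 ± 0.22), Ttll10 (-1.51), Mfsd2a (-2.23) and Ndrg1 (-3.27 ± 0.44, adjusted p = 1.6e-06). The Ttll10 peak (chromosome 4, 156031544 to 156032357) starts just past the end of the Tnfrsf18 peak (156031480). Both losses may therefore belong to a single region that the assignment by distance gave to different genes. A gene end of the IL-4 receptor gene Il4ra fell (116 ± 14.6 to 47.9 ± 11 CPM, -1.25 ± 0.17, adjusted p = 1.3e-06).

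Genes of the Th17 programme lost more peaks than they gained. An Il17f peak fell from 67.3 ± 8.16 to 33.1 ± 0.909 CPM (-1.0 ± 0.21, adjusted p = 0.0015), and an Irf4 peak at a gene end fell from 60.8 ± 9.06 to 28.3 ± 7.96 (-1.10 ± 0.22). Peaks at Stat3, which encodes the transcription factor downstream of IL-6, and at Ahr rose (1.74 ± 0.29, from 6.10 to 21.0 CPM, and 1.22 ± 0.24, from 12.5 to 30.5), while 2 other Stat3 peaks fell. Of 165 Th17-list peaks, 4 rose, 23 fell and the rest did not pass; adjusted over the list alone, 7 rose and 27 fell. The median log2 change was -0.24 (camera adjusted p = 0.0082; adjusted p = 0.573 with an estimated correlation). Of 175 Treg-list peaks, 8 rose and 24 fell (10 and 31 adjusted over the list alone), with losses at Tnfrsf18, Ctla4, Tigit (-1.33) and Tnfrsf9 (-1.11). The Treg-list median was -0.20 (camera adjusted p = 0.0082; adjusted p = 0.052 with an estimated correlation). Naive and memory genes had 5 higher and 22 lower of 212 peaks (7 and 26 adjusted over the list alone; 2 and 19 with DESeq2). Losses were at the chromatin organizer Satb1 (-2.03 ± 0.35), the repressor Bach2 (-2.19) and Ccr7 (-1.38). Their median was -0.17 (camera adjusted p = 0.0101; adjusted p = 0.151 with an estimated correlation).

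The other 13 lists did not pass as sets in Th17n cells (lowest adjusted p = 0.164). Of 58 polyamine peaks 2 rose and 2 fell, the same adjusted over the list alone (adjusted p = 0.698). Eif5a, which encodes the translation factor that carries the polyamine-derived residue hypusine, rose at a gene end from 121 ± 14.1 to 187 ± 13.8 CPM (0.61 ± 0.11, adjusted p = 0.00023). The spermidine synthase gene Srm rose at a gene end (67.9 ± 5.85 to 99.2 ± 4.59 CPM, 0.53 ± 0.13, adjusted p = 0.0075). A peak in the spermine oxidase gene Smox fell from 44.1 ± 3.53 to 15.5 ± 3.52 CPM (-1.52 ± 0.30, adjusted p = 0.00068). The Srm adjusted p reached 0.052 over the other settings and 0.117 without Th17n vehicle of animal 3. Activation and AP-1 genes had 8 higher and 12 lower of 154 peaks (8 and 13 adjusted over the list alone, adjusted p = 0.164), with losses at Fosl2 (-2.18), Nfkb1 (-1.72) and Batf3 (-2.68) and a gain at Nr4a3 (1.18). Th1 genes had 1 and 7 of 82 (5 and 10 alone, adjusted p = 0.164), with losses at Stat4 (-1.48) and Il12rb2 (-1.07). Th2 genes had 0 and 2 of 31 (2 and 4 alone, adjusted p = 0.691), Stat6 (-0.47) and Gata3 (-1.47). Tfh genes had 5 and 3 of 63 (6 and 4 alone, adjusted p = 0.688), among them Tox2 (1.90), Btla (1.62) and Icos (-1.06). TGF-beta and STAT feedback genes had 4 and 8 of 97 (4 and 10 alone, adjusted p = 0.493), with a gain at Socs1 (227 to 337 CPM, 0.56) and a loss at Tgfbr2 (-1.51). Glycolysis genes had 0 and 6 of 63 (1 and 7 alone, adjusted p = 0.493), with losses at Hk2 (-1.14) and Ldha (-1.39). Chromatin modifier genes had 5 and 6 of 103 (9 and 10 alone, adjusted p = 0.698), with Dnmt1 (0.84) and Tet2 (1.55) up and Ezh2 (-1.63) and Tet3 (-1.81) down. Cell cycle genes had 1 and 1 of 92 (0 and 0 alone, adjusted p = 0.688), Cdk6 (1.58) and E2f2 (-0.85). Interferon genes had 1 and 1 of 28 (1 and 1 alone, adjusted p = 0.698), Stat2 (0.49) and Irf8 (-1.07). Lists of other cell types had 0 and 1 of 11 for cytotoxic and NK cells (Klrk1, 1 and 1 alone, adjusted p = 0.879). They had 1 and 0 of 25 for B cells (Blnk, 1.42, 1 and 0 alone, adjusted p = 0.879) and 1 and 0 of 12 for myeloid cells (Spi1, 0.502 to 4.16 CPM, 2.32, 2 and 0 alone, adjusted p = 0.493). With 1 library left out, at least 1 of the 6 choices ended the call at Stat6, Gata3, Btla, Icos, Nr4a3, Tet2, Cdk6, E2f2, Stat2, Klrk1 and Spi1. The Il12rb2 call was lost with DESeq2 (adjusted p = 0.220) and the Tox2 call after thinning (adjusted p = 0.082). Another Btla peak fell, and peaks moved both ways at Nfkb1 (2 up, 5 down) and Bach2 (2 and 4). Median, mean and test differed in sign for 3 of the 16 lists: polyamine (median 0.050, mean -0.010), chromatin modifiers (0.07, -0.01) and B cells (0.12, -0.08).

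Of the fixed genes, Il17a fell at a gene end (chromosome 1, 20730661 to 20731781) from 22.3 ± 3.71 to 8.83 ± 2.29 CPM (-1.28 ± 0.36, adjusted p = 0.019). Its adjusted p was up to 0.024 over the other settings and 0.117 without Th17n vehicle of animal 2. The single Foxp3 peak, inside the gene (chromosome X, 7593219 to 7593658), fell from 15.7 ± 4.47 to 5.38 ± 2.44 CPM (-1.39 ± 0.40, adjusted p = 0.022). There the adjusted p was up to 0.055 over the other settings and 0.099 without Th17n with DFMO of animal 3. A distal Il2ra peak (chromosome 2, 11629681) rose from 3.19 to 10.6 CPM (1.75 ± 0.42, adjusted p = 0.0051), up to 0.137 over the other settings and 0.092 without Th17n vehicle of animal 2. The peak at the end of Odc1, which encodes the enzyme that DFMO inhibits (chromosome 12, 17544271 to 17545482), stayed at 87.4 ± 10.1 and 89.7 ± 5.18 CPM (0.028 ± 0.13, adjusted p = 0.93). No change passed at the peaks nearest the gene ends of Il17f (-0.59), Il23r (-0.56), Il2ra (0.023), Ikzf2 (-0.32), Tbx21 (-0.032), Ifng (-0.32), Sat1 (0.022) and Kdm6b (-0.18). At a distal Ifng peak a gain (1.53) had an adjusted p of 0.045, which reached 0.085 over the other settings and 0.451 without Th17n with DFMO of animal 2.

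In all, 3841 of 43726 peaks (8.78%) passed in Th17n cells, 1968 more and 1873 less accessible with DFMO, and 10138 had an unadjusted p under 0.05. Of these, 1137 gains and 1338 losses were at least 2-fold, and the median size was 1.21 log2 units. Gains lay at gene ends in 26.5% of cases and losses in 12.8%, against 27.5% of peaks that did not pass; losses lay inside gene models in 54.1%. The count of gains fell to 1166, 869 and 728 without Th17n vehicle of animal 1, 2 or 3 and to 748, 1102 and 1080 without Th17n with DFMO of animal 1, 2 or 3. The count of losses fell to 950 and 909 without Th17n vehicle of animal 2 or 3 and to 1022 and 1219 without Th17n with DFMO of animal 1 or 3.

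**Figure D2:**
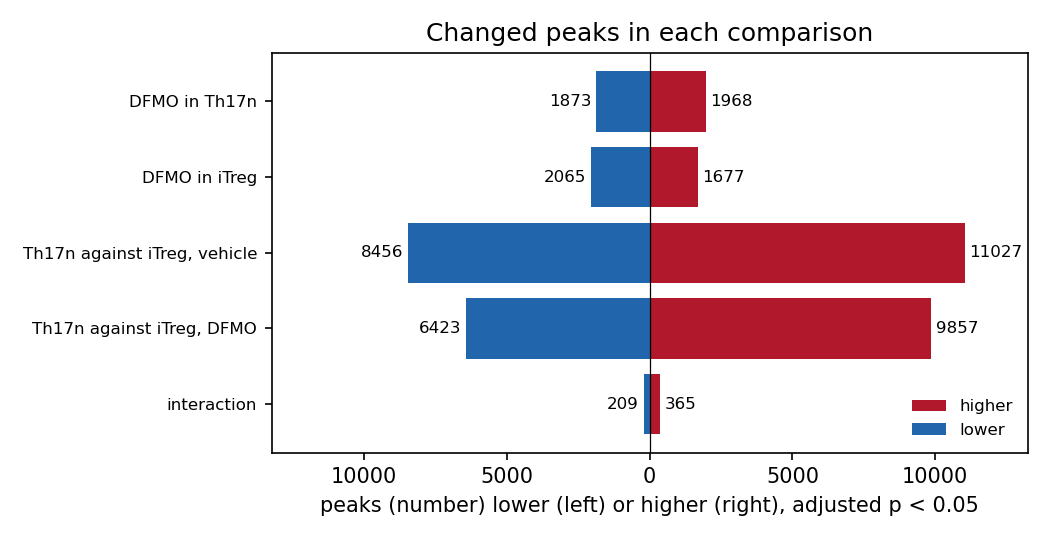
Number of peaks past the adjusted threshold in each comparison, higher to the right and lower to the left; for the lineage comparisons higher means higher in Th17n. DFMO changed 1968 and 1873 peaks in Th17n and 1677 and 2065 in iTreg, against 11027 and 8456 between lineages in vehicle.

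The second question was the same for iTreg cells. A peak inside Esr1, which encodes the estrogen receptor alpha (chromosome 10, 4900172 to 4900706), rose from 2.56 ± 1.04 to 27.2 ± 8.23 CPM (3.52 ± 0.36, adjusted p = 7.9e-09). A peak near Tgfbi, a gene known to be induced by TGF-beta (chromosome 13, 56601202 to 56601973), rose from 14.6 ± 3.17 to 53.7 ± 6.40 CPM (1.89 ± 0.20, adjusted p = 7.9e-09). At a gene end of Fads2, which encodes a fatty acid desaturase (chromosome 19, 10100699 to 10102206), accessibility fell from 99.0 ± 11.2 to 28.8 ± 10.3 CPM (-1.82 ± 0.18, adjusted p = 6.9e-09). The Tnfrsf18 peak that fell in Th17n fell here from 94.5 ± 15 to 39.9 ± 12.1 CPM (-1.23 ± 0.17, adjusted p = 3.7e-06). A peak inside Nrp1, which encodes the Treg surface protein neuropilin-1 (chromosome 8, 128420476 to 128421247), fell from 34.4 ± 11.8 to 10.1 ± 1.78 CPM (-1.83 ± 0.26, adjusted p = 6.7e-06).

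Other strong gains were at Bend4 (13 ± 1.94 to 53.4 ± 17.6 CPM, 2.02 ± 0.23, adjusted p = 1.3e-07), Stx5a (3.0), Golm1 (1.43), Slc1a7 (2.14), Peli2 (1.63) and Tmcc3 (2.16). Other strong losses were at Rassf7 (139.9 ± 5.92 to 45.8 ± 19.6 CPM, -1.65 ± 0.17, adjusted p = 1.1e-08), where the microRNA gene Mir210 lies at the same peak, and at Spcs2 (-1.79 ± 0.20). Further losses were at the actin gene Actg1 (73.9 ± 16.9 to 29.0 ± 4.34 CPM, -1.39 ± 0.18), Pkd2l1 (-1.05), Fgfbp1 (-1.07), Fgd2 (-1.15) and Dnase1l3 (-2.29).

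In iTreg cells 6 of 16 lists passed, all downward, and 1 of them also did with an estimated correlation. Treg-list peaks had 3 gains and 28 losses of 175 (7 and 38 adjusted over the list alone). Among the losses were Tnfrsf18, Nrp1, Tnfrsf9 (50.8 ± 11.3 to 16.1 ± 4.53 CPM, -1.66 ± 0.24) and a gene end of Ctla4 (30.2 ± 4.68 to 10.0 ± 2.85, -1.54 ± 0.27). This was the list that passed with both correlations (camera adjusted p = 0.00063; adjusted p = 0.034 with an estimated correlation; median -0.20). Th17-list peaks had 3 and 18 of 165 (3 and 26 alone, median -0.27). They fell at Rora (33.2 ± 6.30 to 10.5 ± 2.68 CPM, -1.71 ± 0.26), the hypoxia factor gene Hif1a (-2.29 ± 0.41) and Il6ra (-0.91 ± 0.18). Il10 fell as well (-1.13 ± 0.24, adjusted p = 0.0018), up to 0.019 over the other settings and 0.080 without iTreg with DFMO of animal 3. The list had camera adjusted p = 0.00063 and adjusted p = 0.212 with an estimated correlation. Activation and AP-1 peaks had 2 and 17 of 154 (2 and 24 alone, median -0.30), with losses at Fosl2 (43.3 to 17.0 CPM, -1.37), Nfatc1 (-0.84), Jun (-1.12) and Nfkb1 (-0.71). The set had camera adjusted p = 0.00028 and adjusted p = 0.155 with an estimated correlation. Th1 peaks had 1 and 13 of 82 (4 and 16 alone, 1 and 7 with DESeq2, median -0.27), with losses at Stat4 (-1.63) and Il12rb2 (-2.06). As a set they had camera adjusted p = 0.0054, and adjusted p = 0.155 with an estimated correlation. Naive and memory peaks had 4 and 20 of 212 (5 and 28 alone, median -0.16), with losses at Ccr7 (39.0 to 11.7 CPM, -1.75) and Bach2 (-0.73). Together they had camera adjusted p = 0.0153, and adjusted p = 0.155 with an estimated correlation. Glycolysis peaks had 4 and 10 of 63, the same adjusted over the list alone (median -0.21). Losses lay at gene ends of the lactate transporter gene Slc16a3 (38.5 ± 3.39 to 13.5 ± 4.58 CPM, -1.55 ± 0.25) and the glucose transporter gene Slc2a1 (138 ± 6.34 to 88.6 ± 16.9, -0.65 ± 0.14) and at Gapdh (-1.52). Here camera adjusted p = 0.0275, and adjusted p = 0.230 with an estimated correlation.

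The other 10 lists did not pass in iTreg (lowest adjusted p = 0.0781). Polyamine peaks had 2 gains and 2 losses of 58, the same adjusted over the list alone (adjusted p = 0.820). The Amd1 gene encodes adenosylmethionine decarboxylase, and a peak outside it (chromosome 10, 40309891 to 40310773) fell from 24.4 ± 10.0 to 6.28 ± 3.87 CPM (-1.91 ± 0.35, adjusted p = 0.00033). A peak near the antizyme inhibitor gene Azin1 fell (74.1 ± 10.3 to 46.1 ± 6.64 CPM, -0.70 ± 0.15, adjusted p = 0.0013). The Eif5a gene end rose (173 ± 9.87 to 236 ± 11.5 CPM, 0.45 ± 0.11, adjusted p = 0.0045, up to 0.057 over the other settings and 0.048 with 1 library left out), as did Ass1 (0.94). TGF-beta and STAT feedback genes had 7 and 7 of 97 (7 and 10 alone, adjusted p = 0.852), with Ski (0.73) up and Smad3 (-0.65) and Socs3 (-0.89) down. Chromatin modifiers had 3 and 3 of 103 (3 and 3 alone, adjusted p = 0.702), with Ezh2 (2.27) and Smarca4 (1.26) up and Tet2 (-1.11) and Tet3 (-0.78) down. Cell cycle genes had 2 and 3 of 92 (2 and 3 alone, adjusted p = 0.820), with Mcm5 (0.60) and Cdkn1a (0.88) up and Ccnd3 (-1.18) and E2f2 (-1.60) down. Tfh genes had 4 and 3 of 63 (7 and 8 alone, adjusted p = 0.861), with Pdcd1 (1.55) up and Icos (-1.53) down. Th2 genes had 1 and 3 of 31 (1 and 3 alone, adjusted p = 0.124), with Il24 (1.47) up and Ccr8 (-0.81) down. Interferon genes had 0 and 3 of 28 (2 and 8 alone, adjusted p = 0.0781), among them Irf7 (-0.69) and Irf8 (-0.73). B cell genes had 1 and 2 of 25 (1 and 6 alone, adjusted p = 0.820), with Blnk (0.98) and Ebf1 (-1.64). The calls at Il24, Socs3, Ass1, Smarca4, Tet2, Ezh2, Mcm5, E2f2, Cdkn1a, Irf7, Irf8, Blnk and Ebf1 ended with at least 1 library left out. After thinning, the calls at Jun (adjusted p = 0.089), Pdcd1 (0.200) and Smad3 (0.196) were lost, and another Smad3 peak rose. Peaks moved both ways at Socs3 (1 up, 2 down), Rora (2 and 4), Il12rb2 (1 and 2), Nfatc1 (1 and 2), Ccr7 (1 and 3) and Bach2 (1 and 9). With edgeR, 0 peaks passed among 11 of cytotoxic and NK cells (2 had an unadjusted p under 0.05, DESeq2 gave 1; adjusted p = 0.0781) and 0 among 12 of myeloid cells (1 unadjusted, DESeq2 gave 0; adjusted p = 0.132). Signs of median, mean and test differed for 3 lists: Tfh (median -0.04, test upward), polyamine (0.0014, mean -0.11) and B cells (0.15, mean -0.34).

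Of the fixed genes in iTreg, a distal Il17f peak fell (11.1 ± 3.28 to 4.40 ± 0.983 CPM, -1.30 ± 0.33, adjusted p = 0.0085, up to 0.051 over the other settings and 0.065 without iTreg with DFMO of animal 3). A distal Il17a peak fell (40.7 ± 9.93 to 24.8 ± 8.91 CPM, -0.73 ± 0.21, adjusted p = 0.021, in 2 of 3 animals), up to 0.085 over the other settings and 0.331 without iTreg with DFMO of animal 3. A distal Il2ra peak rose (30.9 ± 7.10 to 58.1 ± 19.8 CPM, 0.93 ± 0.21, adjusted p = 0.0036), up to 0.027 over the other settings and 0.067 without iTreg vehicle of animal 3. Of the 15 Il2ra peaks 1 rose and 3 fell. No change passed at Foxp3 (0.15 ± 0.44, adjusted p = 0.89) or at the Odc1 gene end (109 ± 3.57 and 124 ± 15.6 CPM, 0.19 ± 0.12, adjusted p = 0.39). Nor did it at the peaks nearest the ends of Il17a (1.49), Il17f (0.14), Il23r (-0.46), Il2ra (-0.032), Ikzf2 (0.11), Tbx21 (-0.64), Ifng (-0.38), Sat1 (0.023) and Kdm6b (-0.14).

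In iTreg cells 3742 peaks (8.56%) passed, 1677 more and 2065 less accessible with DFMO, and 9963 had an unadjusted p under 0.05. Changes of at least 2-fold numbered 955 gains and 1232 losses, and the median size was 1.12. Gains lay at gene ends in 25.8% and losses in 20.6%. The gains fell to 774 and 649 without iTreg vehicle of animal 2 or 3 and to 621 without iTreg with DFMO of animal 3. The losses fell to 1089 and 778 without iTreg vehicle of animal 2 or 3 and to 1272 and 795 without iTreg with DFMO of animal 1 or 3.

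**Figure D3:**
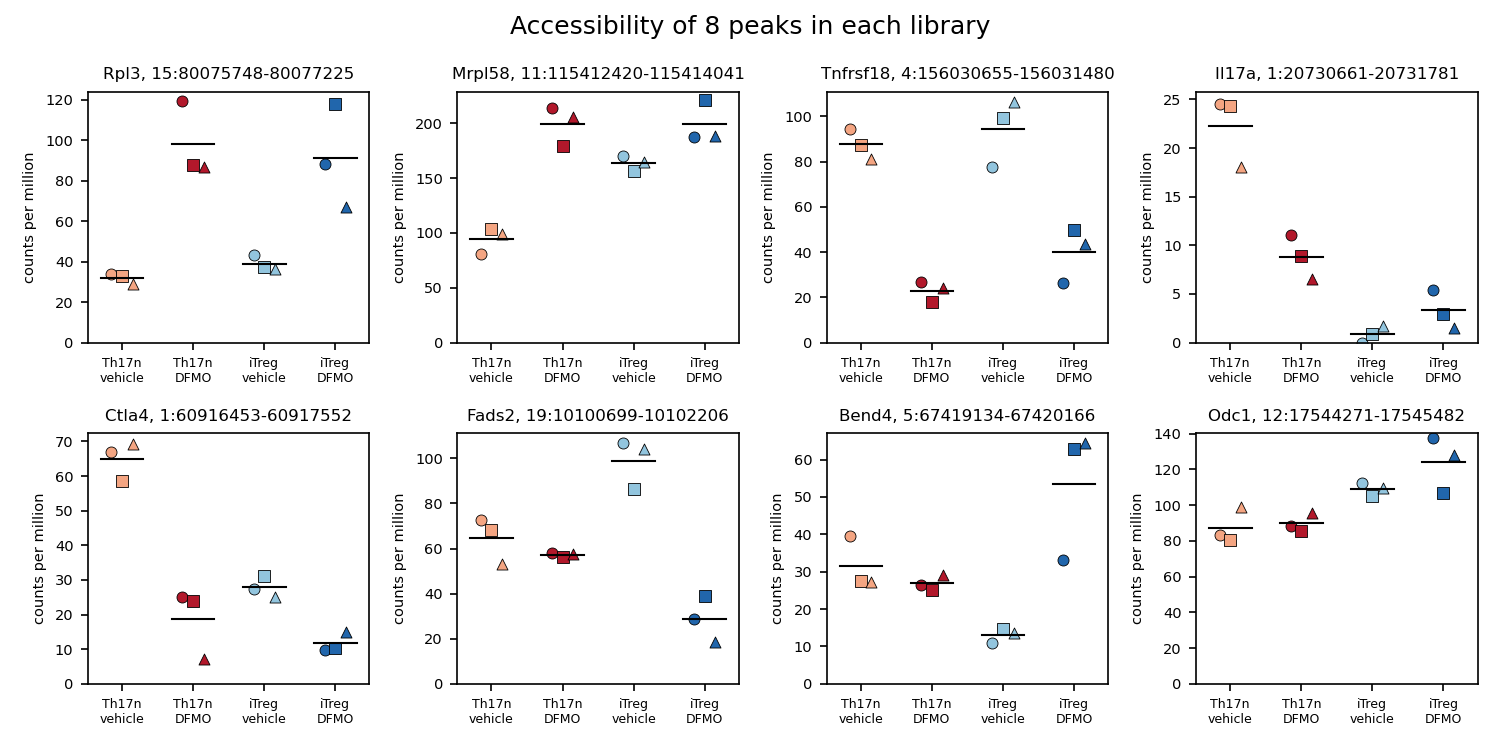
Accessibility (CPM) at 8 peaks in each library (points, shaped by animal) with the group mean (line). The Tnfrsf18 peak falls with DFMO in both lineages (87.7 to 22.9 and 94.5 to 39.9), while Fads2 falls in iTreg (99.0 to 28.8) and Odc1 moves in neither past the threshold.

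The next question was how far both cell types respond alike. Rpl3 rose in both (31.9 to 98.0 CPM in Th17n and 39.0 ± 3.95 to 91.3 ± 25.6 in iTreg, log2 changes 1.65 and 1.23), and Tnfrsf18 and Zmiz1 fell in both (Zmiz1 -2.41 and -1.74). Esr1 rose in both as well, by 1.59 in Th17n and 3.52 in iTreg. Of the peaks that passed, 348 rose in both lineages (75.5 expected if independent) and 399 fell in both (88.5 expected). Only 26 rose in Th17n and fell in iTreg (92.9 expected), and 14 did the opposite (71.8 expected). Over all tested peaks the log2 changes correlated at r = 0.285 (Spearman rho 0.292), with the same sign at 61.1% of peaks, and these effects share no library. Among peaks that passed in Th17n, r was 0.488 with 76.3% of the same sign. In single animals r was 0.024, 0.251 and 0.215, so animal 1 showed next to none of it.

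The interaction asked where the DFMO effect differs between the lineages. A peak inside Psma6, which encodes a proteasome subunit (chromosome 12, 55392950 to 55393563), rose from 18.1 ± 1.59 to 49.3 ± 8.63 CPM in Th17n and fell from 35.1 ± 5.71 to 19.2 ± 4.09 in iTreg (difference 2.28 ± 0.31, adjusted p = 3e-05). A peak near the heat shock gene Hspb8 (chromosome 5, 116380623 to 116381714) went from 28.7 ± 4.23 to 10.2 ± 3.29 CPM in Th17n and from 4.44 ± 0.821 to 15.4 ± 4.53 in iTreg (-3.30 ± 0.46, adjusted p = 3e-05). At a gene end of Atm, which encodes a DNA damage kinase (chromosome 9, 53435559 to 53436419), the values went from 42.4 ± 9.84 to 17.3 ± 3.75 CPM and from 3.21 ± 0.491 to 11.2 ± 4.04 (-3.15 ± 0.45, adjusted p = 5.1e-05). The Fads2 peak stayed at 64.7 ± 10.4 and 57.3 ± 0.920 CPM in Th17n while it fell in iTreg (1.67 ± 0.25, adjusted p = 0.00012). Bend4 stayed at 31.5 ± 7.08 and 26.9 ± 2.08 while it rose in iTreg (-2.19 ± 0.33, adjusted p = 0.00012). In all, 574 peaks (1.31%) passed, 365 with the higher DFMO effect in Th17n and 209 with the higher in iTreg; 6094 had an unadjusted p under 0.05. With RLE factors the split was 285 and 251 (53.2% against 63.6% higher).

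The count of 574 depended on single libraries. It fell to 344, 314 and 192 without Th17n vehicle of animal 1, 2 or 3 and to 232, 371 and 340 without Th17n with DFMO of animal 1, 2 or 3. It fell to 324 and 334 without iTreg vehicle of animal 2 or 3. It was 329 and 260 without iTreg with DFMO of animal 1 or 3 and rose to 1370 without that of animal 2. No gene list passed in the interaction (adjusted p = 0.519 or higher; 0.789 or higher with an estimated correlation). Th17 genes had 4 higher and 2 lower peaks (8 and 4 adjusted over the list alone, adjusted p = 0.650) and naive and memory genes 2 and 2 (0 and 2 with DESeq2, adjusted p = 0.794; test downward, median 0.0064). Treg genes had 2 and 0 (0 and 0 with DESeq2, adjusted p = 0.775), glycolysis genes 2 and 0 (5 and 1 alone, adjusted p = 0.650) and chromatin modifiers 0 and 1 (2 and 2 alone, adjusted p = 0.650). Th1 (adjusted p = 0.650), Tfh (0.712) and TGF-beta and STAT feedback genes (0.650) had 1 and 0 each. With edgeR 0 peaks passed in 8 lists, where DESeq2 also gave 0. Those with an unadjusted p under 0.05, higher and lower, were 21 and 3 for activation and AP-1, and in the same way polyamine (10 and 4), B cell (5 and 1), cytotoxic and NK (2 and 3), cell cycle (1 and 3), Th2 (2 and 0), interferon (2 and 0) and myeloid genes (1 and 0; median -0.15, mean 0.04). At the fixed genes, Il17a at a gene end passed (-2.78 ± 0.71, adjusted p = 0.033, up to 0.051 over the other settings and 0.160 without iTreg with DFMO of animal 1). The iTreg part of this difference did not pass on its own and started from 0 to 1.66 CPM in vehicle. Foxp3 (-1.54 ± 0.60, adjusted p = 0.21), Odc1 (-0.16), Il17f (-0.73), Il23r (-0.10), Il2ra (0.054), Ikzf2 (-0.42), Tbx21 (0.61), Ifng (0.062), Sat1 (-0.00079) and Kdm6b (-0.042) did not.

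The comparison of lineages in vehicle asked what separates Th17n from iTreg without the drug. The Il21 gene end, at a cytokine gene of Th17 and follicular helper cells (chromosome 3, 37231027 to 37231695), had 55.3 ± 1.75 CPM in Th17n and 2.45 ± 2.20 in iTreg (4.30 ± 0.32, adjusted p = 2.9e-15). The Il17a gene end had 22.3 ± 3.71 against 0.850 ± 0.832 CPM (4.36 ± 0.47, adjusted p = 1.4e-10), and all 5 Il17a and all 5 Il17f peaks were higher in Th17n. A peak inside Frmd6 (chromosome 12, 70890603 to 70891791) had 105 ± 9.91 against 3.71 ± 1.34 CPM (4.73 ± 0.23, adjusted p = 5.5e-21), the smallest adjusted p of the comparison. Higher in iTreg were a peak near Papolg (14.6 ± 5.06 against 100.5 ± 3.56 CPM, -2.65 ± 0.19, adjusted p = 8.9e-16) and a peak in Ppfibp2 (2.11 ± 1.85 against 44.6 ± 4.13, -4.02 ± 0.32). So was a gene end of Selplg, which encodes the P-selectin ligand PSGL-1 (13.6 ± 1.79 against 64.2 ± 5.42, -2.19 ± 0.18, adjusted p = 1.5e-13). Other strong differences were Vstm5 (5.29), Cdc73 (3.72), Stard13 (4.47), Tmtc4 (5.46), Arid1b (4.34) and Epg5 (5.17) towards Th17n. Towards iTreg they were Mxd1 (-2.75), Emsy (-2.38), Colq (-3.83), Hbs1l (-3.65) and Agr3 (-2.82).

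Th17-list peaks were higher in Th17n in 78 cases and lower in 26 of 165 (80 and 26 adjusted over the list alone), led by Il21, Rora (4.81 ± 0.37), Il17f (2.63 ± 0.23) and a distal Il17a peak (3.67 ± 0.34). Their median was 0.61 (camera adjusted p = 0.0044; adjusted p = 0.616 with an estimated correlation). Treg-list peaks were split, 41 higher and 41 lower of 175, the same adjusted over the list alone (adjusted p = 0.928). Higher in Th17n were peaks at Ctla4 (23.7 ± 5.02 against 0.973 ± 0.699 CPM, 4.48), Entpd1 (2.20), Nt5e (2.60) and a gene end of Il2ra (1.82 ± 0.21), where 2 peaks were higher and 4 lower in all. Foxp3 was higher in Th17n (15.7 ± 4.47 against 4.39 ± 2.29 CPM, 1.65 ± 0.39, adjusted p = 0.00049), while a weak peak near Ikzf2 was lower (0.489 ± 0.442 against 7.01 ± 2.23, -3.45 ± 0.63). The remaining lists did not pass (lowest adjusted p = 0.0771). They had 15 and 26 of 82 peaks for Th1 (adjusted p = 0.414), with Stat4 (-4.54) and Il18r1 (-2.93) higher in iTreg. The numbers were 4 and 13 of 28 for interferon genes (4 and 14 alone, adjusted p = 0.0771), with Irf7 (-0.99) and Stat2 (-0.69; adjusted p = 0.065 after thinning) higher in iTreg and Oasl2 (2.36) in Th17n. For Th2 they were 6 and 11 (Gata3 2.66, Ccr8 -2.10, adjusted p = 0.533), for Tfh 18 and 11 (Btla 3.78, Icos -1.96, adjusted p = 0.928) and for naive and memory genes 60 and 40 (Satb1 2.99, Lef1 -2.06, adjusted p = 0.928). For activation and AP-1 genes they were 34 and 39 (Nfkb1 3.87, Fosl2 3.57, adjusted p = 0.928) and for TGF-beta and STAT feedback 20 and 26 (Smad3 4.14, Socs2 -0.91, adjusted p = 0.533). Polyamine genes had 16 and 16 (9 lower with DESeq2, Smox 2.31, Slc7a1 -2.81, adjusted p = 0.928), chromatin modifiers 36 and 27 (Crebbp 3.36, Smarca4 -3.68, adjusted p = 0.940). Metabolic genes of glycolysis had 14 and 17 (Pdk1 3.85, Aldoa -0.65, adjusted p = 0.720) and cell cycle genes 22 and 19 (11 lower with DESeq2, Cdkn2a 4.05, Cdkn1a -2.19, adjusted p = 0.870). Single peaks did not speak for the gene at Gata3 (1 higher and 4 lower), Icos (4 and 4), Smarca4 (2 and 2) and Pdk1 (1 and 1). The lists of other cell types had 4 and 3 of 11 (cytotoxic and NK, adjusted p = 0.928), 10 and 5 of 25 (B cell, adjusted p = 0.533, Ebf1 4.27) and 2 and 3 of 12 (myeloid, adjusted p = 0.928, Spi1 -3.36). Median, mean and test differed in sign for 9 of these lists, among them Treg (median 0.0054, mean 0.11, test downward) and polyamine (median -0.24, mean 0.22).

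A peak outside Odc1 (chromosome 12, 17542557) was far higher in Th17n (26.6 ± 0.964 against 1.27 ± 1.49 CPM, 4.07 ± 0.41, adjusted p = 2.9e-11). The Odc1 gene end was lower (87.4 against 109 CPM, -0.31 ± 0.13, adjusted p = 0.039), but with abundance-trended offsets it was 0.050 (adjusted p = 0.790). The Kdm6b gene end was lower in Th17n (57.9 ± 4.15 against 90.3 ± 2.08 CPM, -0.62 ± 0.14, adjusted p = 0.00028; up to 0.068 over the other settings). The Tbx21 gene end was lower too (14.1 ± 2.16 against 23.1 ± 1.87, -0.67 ± 0.27, adjusted p = 0.038; up to 0.125 over the other settings and 0.194 without Th17n vehicle of animal 3). A distal Tbx21 peak was higher instead (23.0 ± 1.18 against 13.7 ± 2.47, 0.70 ± 0.27, adjusted p = 0.034), up to 0.055 over the other settings and 0.105 without iTreg vehicle of animal 1. Il17f (3.76 ± 0.55) and Il23r (3.24) were higher at gene ends, and so was a peak inside Il23r (1.98 ± 0.30, adjusted p = 6.2e-07). The peaks nearest a gene end at Il2ra (-0.022), Ikzf2 (-0.39), Ifng (0.55) and Sat1 (-0.25) did not pass there. A weak Ifng peak was higher in iTreg (-3.71 ± 0.62, adjusted p = 3.2e-06).

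In vehicle 19483 peaks (44.6%) differed between lineages, 11027 higher in Th17n and 8456 higher in iTreg, and 22348 had an unadjusted p under 0.05. Peaks higher in Th17n lay at gene ends in 4.08% and inside gene models in 57.1%, and those higher in iTreg lay at gene ends in 45%. The iTreg count fell to 5306 without Th17n vehicle of animal 3. Under DFMO, 16280 peaks (37.2%) differed, 9857 higher in Th17n and 6423 higher in iTreg. At the Il17a gene end the means under DFMO were 8.83 ± 2.29 CPM in Th17n and 3.31 ± 1.96 in iTreg (1.58, adjusted p = 0.0066).

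The last question was what DFMO does at the regions that tell the lineages apart. In Th17n cells its effects ran against the cells' own lineage. Specific here means only past an adjusted p of 0.05 for the averaged lineage difference, as 24336 of 43726 peaks were (55.7%). Many differ little: 4517 of the 11216 iTreg-specific peaks lay within 0.5 log2 units (median -0.39). Among the 13120 Th17n-specific peaks 422 did (median 0.42). Of the 1968 peaks that rose, 1024 (52.0%) were iTreg-specific (505 expected if independent) and 361 Th17n-specific (590 expected). Of the 1873 that fell, 1141 (60.9%) were Th17n-specific (562 expected) and 195 iTreg-specific (480 expected). The Il17a, Il17f and Irf4 losses above belong to the Th17n-specific side, and the Stat3 and Ahr gains lay at peaks higher in iTreg vehicle (39.5 ± 6.85 and 36.7 ± 5.68 CPM against 6.10 ± 0.824 and 12.5 ± 1.96). The same Th17n vehicle values enter the gains and the vehicle comparison, so the Stat3 and Ahr peaks are examples and not separate support. Of 13120 Th17n-specific peaks, 63.8% were lower with DFMO (median -0.21; camera p = 2.2e-07, p = 0.040 with an estimated correlation). Of 11216 iTreg-specific peaks, 67.6% were higher (median 0.16; p = 2.6e-08, p = 0.0011 with an estimated correlation). The slope of the DFMO effect on the lineage effect was -0.165 (r = -0.351), and in the 3 animals -0.174, -0.0876 and -0.190 (mean -0.151 ± 0.0552, SD, n = 3). Simulation without a DFMO effect gave slopes of 0.0028 to 0.010.

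**Figure D4:**
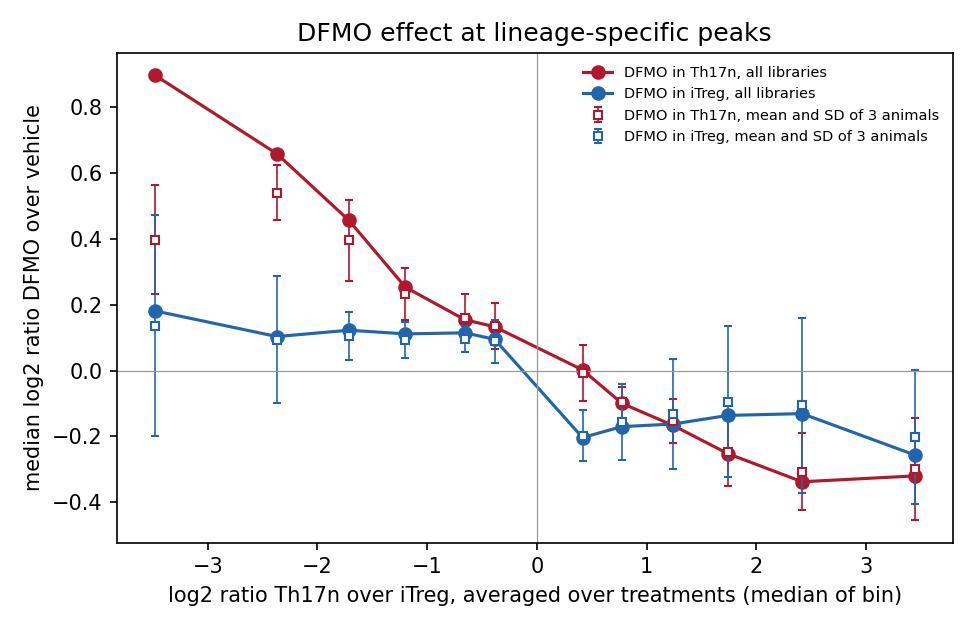
Median log2 change with DFMO (filled points, all libraries; open squares, mean ± SD of 3 animals) for lineage peaks binned by their log2 ratio of Th17n over iTreg. In Th17n the medians run from 0.90 at the most iTreg-specific 151 peaks to -0.32 at the most Th17n-specific 1385, and in iTreg from 0.18 to -0.26. The means of 3 animals at these ends are 0.40 ± 0.16 and -0.30 ± 0.15 in Th17n and 0.14 ± 0.34 and -0.20 ± 0.20 in iTreg.

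In iTreg cells the pattern was weaker and depended on the list. With the list averaged over treatments, 810 of the 1677 peaks that rose (48.3%) were iTreg-specific (430 expected) and 897 of the 2065 that fell (43.4%) were Th17n-specific (620 expected). Th17n-specific peaks were lower in 58.2% (median -0.16; camera p = 0.022, p = 0.317 with an estimated correlation) and iTreg-specific peaks higher in 62.4% (median 0.11; p = 5.2e-05, p = 0.013 with an estimated correlation). The Hif1a peak (11.4 to 2.19 CPM), higher in Th17n than in iTreg in vehicle (27.6 ± 2.00 against 11.4 ± 4.5), was among the losses. The slope was -0.0898 (r = -0.177), where simulation without a DFMO effect gave -0.022 to -0.015, but it was 0.028, -0.0716 and -0.134 in the 3 animals, so its sign was not shared. With the list from vehicle libraries alone it was 0.040, just above the 0.032 to 0.038 that simulation gave without a DFMO effect. No direction is therefore given for lineage peaks in iTreg.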

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

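The peaks below were picked out because the DFMO effect differed between Th17n and iTreg in the interaction test, which was planned. Thinning and abundance-trended offsets, which are among the other settings below, were added after the data were seen. Every value below is the log2 DFMO effect in Th17n minus that in iTreg, for 3 animals in each of 4 groups. In all, 574 peaks passed.

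At Psma6 the difference was 2.28, from an effect of 1.42 in Th17n and -0.86 in iTreg. At Shld2, a DNA repair gene, it was 4.06 (2.81 and -1.25), at Rab38 4.17 (2.32 and -1.85), at Ccser1 2.75 (0.91 and -1.84) and at Aim2, which encodes a DNA sensor, 1.97 (1.22 and -0.75). At Fads2 it was 1.67, at Spcs2 1.93 (0.14 and -1.79) and at Smg1 2.45 (0.07 and -2.39). In the other direction it was -3.30 at Hspb8 (-1.45 and 1.85), -3.15 at Atm (-1.35 and 1.80), -2.03 at Uvrag (-0.92 and 1.11) and -2.10 at Ripor2 (-1.69 and 0.41). At Bend4 it was -2.19, at Cep70 -2.93 (-0.13 and 2.80), at Peli2 -1.76 (-0.13 and 1.63) and at Srgap3 -2.36 (-0.50 and 1.85).

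Genes of the lists differed too. A peak in Il6ra, which encodes the IL-6 receptor, differed by 1.37 (0.46 in Th17n and -0.91 in iTreg), the Stat3 peak by 1.61 (1.74 and 0.13) and the Ahr peak by 1.22. The Il17a gene end differed by -2.78 (-1.28 and 1.49). Its iTreg change did not pass and rests on few counts. In animals 1, 2 and 3 it held 0, 0.889 and 1.66 CPM in iTreg vehicle and 5.42, 2.97 and 1.54 with DFMO. Among other T cell genes the difference was 1.34 at Nrp1 (-0.48 and -1.83), 1.76 at Stat4 (0.13 and -1.63), 2.48 at Btla (1.62 and -0.86), -2.48 at Bach2 (-0.49 and 1.99), -2.40 at Satb1 (-2.03 and 0.36) and 1.42 at Ccr7 (0.37 and -1.05). It was 0.82 at Smad3 (0.17 and -0.65), -2.36 at Ep300 (-0.93 and 1.43), 1.46 at Slc16a3 (-0.09 and -1.55) and 0.99 at Pfkp (0.42 and -0.57). With 1 library left out, Il6ra alone among these list genes stayed past the threshold throughout (adjusted p up to 0.0253). The adjusted p reached 0.160 at Il17a (up to 0.051 over the other settings), 0.0759 at Stat3 (0.051), 0.158 at Ahr (0.056), 0.168 at Nrp1 (0.251) and 0.0581 at Bach2 (0.080). After thinning it reached 0.091 at Smg1.

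Other splits of the 12 libraries were tried to see how many peaks they give. They mix vehicle and DFMO libraries within groups, which can raise the estimated spread. Their counts therefore do not measure what chance alone gives. Of 30 splits drawn from 200, 1 gave 574 or more, the real one, and the highest other gave 293. Among the 5 others that part as many pairs of animals, the highest gave 137. The split that exchanges treatment labels within a single lineage was not among those drawn.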

How the results depend on the processing

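Thinning, abundance-trended offsets and the gene classes were tests added after the data were seen; the cause was not tested except where named. Counts of changed peaks over all tested peaks stayed within 1.5 times their value with DESeq2, RLE factors, library totals, no filter, autosomes only and abundance-trended offsets. Counts within a gene list or class moved more in some cases. DESeq2 gave 3131 peaks for DFMO in Th17n (3088 shared in the same direction), 3126 in iTreg (3022 shared) and 463 for the interaction (433 shared). With the animal as a block the counts were 1957 and 1772 for DFMO in Th17n, 1623 and 2056 in iTreg and 686 for the interaction, of which 3515, 3553 and 557 were shared. Of 256 named peaks past the threshold, 198 stayed past it in every setting that tested them. Not all settings tested all: 236 were tested at 30 counts, 242 after thinning, 254 on autosomes and 222 with only the libraries compared. With any library left out, 189 stayed past it. Of the 256, 1 changed sign (Odc1 between lineages). Of 50 named peaks not past it, 8 passed in some setting.

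Fewer counts gave fewer peaks by construction. Thinned to the smallest total, DFMO changed 912 (more) and 985 (less) in Th17n and 629 and 731 in iTreg, the lineages differed at 6579 and 3920 peaks in vehicle and 6243 and 3377 under DFMO, and the interaction held 185. At an adjusted p of 0.01 the counts were 768 and 690, 611 and 828, 5315 higher in iTreg in vehicle, 3594 under DFMO, and 139 for the interaction. With at least 30 counts in 3 libraries, fewer peaks were tested, and 7206 and 4110 differed between lineages in vehicle and 4264 were higher in iTreg under DFMO. With only the libraries compared, 2988 peaks fell in Th17n and 1371 in iTreg with DFMO; the cause was not tested. With 1 library left out, gains ran from 728 to 1166 and losses from 909 to 1724 in Th17n, from 621 to 1791 and 778 to 2601 in iTreg. Lineage counts ran from 9688 to 11345 and 5306 to 7959 in vehicle and from 7739 to 9695 and 4872 to 6504 under DFMO, and the interaction from 192 to 1370.

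The slope of DFMO in Th17n on the lineage effect was -0.237 with the vehicle list, which shares libraries with it, and -0.213 to -0.128 with 1 library left out. In iTreg the slope turned to 0.040 with that list, where sharing alone gives 0.0341 on average, and ran from -0.160 to 0.0107 with 1 library left out (highest without iTreg vehicle of animal 3).

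For DFMO in Th17n 3 gene lists passed, 0 with an estimated correlation and 0 with peaks within 1 kb of a gene end. In iTreg 6 passed, 1 with an estimated correlation and 2 with peaks within 1 kb. Between lineages in vehicle 1 passed, 0 with an estimated correlation, 4 with fry and 6 with peaks within 1 kb. In the interaction 0 passed and 1 with peaks within 1 kb. Fewer peaks enter within 1 kb; beyond that the cause was not tested.

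The sign of 18 single peaks changed in some setting, 17 of them not past the threshold, and the cause was not tested. The Odc1 gene end between lineages (-0.31) was 0.050 with abundance-trended offsets and 0.053 with the block added. With DFMO in Th17n, the Il2ra gene end (0.023) was -0.0045 with DESeq2, -0.0084 with RLE, -0.0015 with totals, -0.018 unfiltered, -0.0070 at 30 counts, -0.014 with the block, -0.020 on autosomes, -0.074 with abundance-trended offsets, -0.11 with these and the block, -0.015 thinned and -0.13 to 0.13 with 1 library left out. Odc1 (0.028) was -0.0037 with DESeq2, -0.0032 with RLE, -0.012 unfiltered, -0.0019 at 30 counts, -0.014 on autosomes, -0.11 with abundance-trended offsets, -0.11 with these and the block, -0.16 thinned and -0.086 to 0.096 with 1 left out. Sat1 (0.022) was -0.015 with DESeq2, -0.0090 with RLE, -0.0028 with totals, -0.019 unfiltered, -0.0075 at 30 counts, -0.023 with abundance-trended offsets, -0.033 with these and the block, -0.42 thinned and -0.11 to 0.11 with 1 left out. Tbx21 (-0.032) was 0.039 thinned and -0.29 to 0.14 with 1 left out, and Ifng ran from -0.59 to 0.0082 with 1 left out.

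With DFMO in iTreg, 1 library left out gave -1.41 to 1.80 at Il17f, -0.98 to 0.22 at Il23r, -0.091 to 0.55 at Foxp3, -0.11 to 0.097 at the Il2ra gene end (0.020 at 30 counts) and -0.19 to 0.17 at Sat1 (-0.035 thinned). Between lineages the Il2ra gene end (-0.022) was 0.026 with DESeq2, 0.035 with RLE, 0.049 with totals, 0.13 at 30 counts, 0.00084 with the block, 0.014 on autosomes, 0.29 with abundance-trended offsets, 0.31 with these and the block and -0.13 to 0.10 with 1 left out. In the interaction, 1 library left out gave -2.40 to 0.78 at Il17f, -0.77 to 0.43 at Il23r, -0.10 to 0.16 at Il2ra, -0.29 to 0.37 at Ifng, -0.15 to 0.17 at Sat1 and -0.17 to 0.044 at Kdm6b. There Il2ra was -0.00011 with RLE, -0.027 at 30 counts, -0.0088 with abundance-trended offsets and -0.046 with these and the block. Il23r was 0.13 with abundance-trended offsets, 0.13 with these and the block and 2.23 thinned. Ifng was -0.0072 with DESeq2, -0.020 at 30 counts and -0.014 with abundance-trended offsets, Sat1 0.010 with the block and Kdm6b 0.091 thinned.

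Offsets for GC content, alone or with the block, and motif content were not run. Depth limits what can be seen: the shallowest library held 1020937 counts, and thinning all libraries to that total gave fewer changed peaks. On simulated data 2-fold changes were recovered in 44.8% of cases for DFMO in Th17n and 7.46% for the interaction. Only 200 peaks and the Treg list were changed there, which makes the adjusted threshold stricter than in the data. These shares therefore do not measure what depth hides.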

Other observations

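The gene class tests were chosen only after the strongest changes had been seen, and so were the depth test of the likeness of both DFMO effects and the random lists drawn from gene ends alone.

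Peaks at tRNA genes gained accessibility with DFMO in Th17n: of 151 tested peaks, 89 rose and 0 fell, with a median log2 change of 0.71 (0.86, 0.57 and 0.67 in the 3 animals; adjusted p = 0.0055 with an estimated correlation). At an isoleucine tRNA gene, n-TItat14 (chromosome 13, 21896723 to 21897117), the gain was 3.42 ± 0.44 (SE, adjusted p = 7.4e-07). In iTreg 30 rose and 0 fell, with a median of 0.37 (0.17, 0.41 and 0.38; adjusted p = 0.049 with an estimated correlation), among them n-TYgta5 (1.90 ± 0.30). The Th17n gains fell to 53 without Th17n vehicle of animal 3 and to 51 without Th17n with DFMO of animal 1. The iTreg gains fell to 13 without iTreg vehicle of animal 3 and to 15 without iTreg with DFMO of animal 3. Without chromosome 13 the iTreg median was 0.24, with 17 gains among 104 peaks. Thinning left 18 iTreg gains, and 1 peak fell without iTreg vehicle of animal 1 or iTreg with DFMO of animal 2. The interaction gave a median difference of 0.42 with 6 higher and 0 lower (adjusted p = 0.049 with an estimated correlation). In vehicle 90 of these peaks were lower and 1 higher in Th17n than in iTreg (median -0.56, adjusted p = 0.044 with an estimated correlation). The same Th17n vehicle libraries enter the Th17n gain, the interaction and this vehicle difference, so these results are not independent. Part of the vehicle difference is shared by peaks of like strength, width and place. Matched random lists had a median of -0.22 (lowest -0.34), and those from gene ends alone -0.33 (lowest -0.41).

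Peaks at snRNA genes, a class that includes spliceosomal RNA genes, rose in 30 and fell in 1 of 38 cases in Th17n. The median was 0.86 (adjusted p = 0.019 with an estimated correlation), and gains lay at Rnu2-10 (1.21), Rnu5g (1.07) and Rnu1a1 (1.03). In iTreg 10 rose and 0 fell (median 0.32; adjusted p = 0.0997 with an estimated correlation), and the difference between lineages had adjusted p = 0.071 with an estimated correlation. In animal 1 the iTreg median was -0.03. The iTreg gains fell to 5 and 3 without iTreg vehicle of animal 2 or 3 and to 3 and 5 without iTreg with DFMO of animal 2 or 3, with a median of 0.19 without DFMO of animal 2. Clustered histone genes rose at 26 of 39 peaks in Th17n with 0 losses (median 0.66; adjusted p = 0.054 with an estimated correlation), such as H1f3 (0.95 ± 0.12, adjusted p = 5.6e-07). Of these 39 peaks only 3 lie outside chromosome 13, and 1 of them rose. The gains fell to 17 without Th17n vehicle of animal 1 and to 13 without Th17n with DFMO of animal 1. In iTreg edgeR passed 0 of them (1 had an unadjusted p under 0.05, DESeq2 gave 0; median 0.0095, and -0.013 and -0.032 with library totals and abundance-trended offsets). The animals did not go the same way there (-0.38, 0.23 and 0.12), and 3 peaks fell without iTreg with DFMO of animal 2 (median -0.11). Their interaction had 11 higher and 0 lower peaks (5 higher with DESeq2; median 0.63, and 1.45, 0.20 and 0.51 in the 3 animals; adjusted p = 0.073 with an estimated correlation). All 52 peaks at genes named as histones had 29 gains and 0 losses in Th17n (median 0.57; adjusted p = 0.049 with an estimated correlation) and 0 and 0 in iTreg (4 had an unadjusted p under 0.05 with edgeR, DESeq2 gave 0). Their Th17n gains fell to 19 without Th17n vehicle of animal 1 and to 14 without Th17n with DFMO of animal 1. Without chromosome 13 their Th17n median was 0.32, with 4 gains among 16 peaks, and 0 of the 16 passed in the interaction. Most of the histone gain therefore lies on the chromosome that holds the large tRNA cluster. Class counts of the interaction were not run with a library left out.

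Cytosolic ribosomal protein genes rose at 17 of 81 peaks in Th17n and at 10 in iTreg with 0 losses in either (median 0.27 in both; adjusted p = 0.026 and 0.044 with an estimated correlation). The Th17n gains fell to 7, 8 and 4 without Th17n vehicle of animal 1, 2 or 3 and to 4, 9 and 5 without Th17n with DFMO of animal 1, 2 or 3. The Th17n median was 0.15 without DFMO of animal 1. The iTreg gains fell to 5 and 4 without iTreg vehicle of animal 2 or 3 and to 4 without iTreg with DFMO of animal 3. Without iTreg with DFMO of animal 2 there were 12 gains and 2 losses. Thinning left 8 gains in Th17n and 4 in iTreg, and abundance-trended offsets left 11 in Th17n. Examples were Rps18 (0.96), Rps14 (0.82), Rps19 (0.55 in Th17n and 0.57 in iTreg) and Rpl10 (0.65 and 0.63). In the interaction 0 passed (6 higher and 1 lower with an unadjusted p under 0.05 in edgeR, DESeq2 gave 0). With an estimated correlation no shift passed for snoRNA genes (4 and 3 of 45 in Th17n, adjusted p = 0.226, and 3 and 1 in iTreg, adjusted p = 0.181) or miRNA genes (9 and 4 of 109, 3 and 5 with abundance-trended offsets, adjusted p = 0.094, and 6 and 8, adjusted p = 0.885). For lncRNA genes the numbers were 260 and 256 of 5880 in Th17n (adjusted p = 0.890) and 249 and 279 in iTreg (adjusted p = 0.885). With the preset correlation snoRNA genes did pass in iTreg (median 0.18, adjusted p = 0.048), but matched random lists reached 0.20, and 0.26 from gene ends alone. None of the 65 rRNA genes had a peak.

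Some genes had several changed peaks; those named were picked for it from all genes, and whether this exceeds chance was not tested. With DFMO in Th17n, Rftn1, which encodes a lipid raft protein of lymphocytes, lost 8 of 18 peaks and gained 0, Zmiz1 lost 6 of 30 and the ubiquitin ligase gene Cblb 5 of 16. Cradd gained 6 of 15 and lost 0, Tex14 6 of 11 and Zfp184 6 of 7, while Il2ra gained 3 and lost 3 of 15. Peaks are counted here under the nearest protein-coding gene. How many of these gained peaks also lie at tRNA, snRNA or histone genes was not tested, so the gains are not assigned to the named genes alone. In iTreg, Bach2 lost 9 of 50 and gained 1, Sla, which encodes an adaptor that dampens T cell receptor signals, lost 7 of 12, Cd47 6 of 21, Ctla4 5 of 16 and Cd83 5 of 10.

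The first pattern weighed is that DFMO in Th17n ran against the lineage difference (slope -0.165). If libraries differing in how counts concentrate in strong peaks were the cause, abundance-trended offsets would remove it. With them the slope stayed at -0.159. These offsets follow peak strength alone. The share of counts at gene ends also differed (46.4% in Th17n vehicle, 48.6% in Th17n with DFMO and 55.3% in iTreg vehicle). Whether that share contributes to the slope was not tested. Unequal precision of the groups gave slopes of only 0.0028 to 0.010 in simulation with peaks drawn independently. Variation shared by the peaks of a library was not simulated, so chance at the level of libraries is not excluded. The shallowest library (Th17n vehicle of animal 1) is not the cause, since the slope was -0.172 without it. A biological explanation within the design, that DFMO moves Th17n accessibility part of the way towards iTreg, is consistent with the slope of -0.159. A lower share of well-differentiated Th17n cells in the culture could give the same, and cell composition was not tested. Movement towards iTreg here refers to the peaks that differ between the cultures, and not to Treg genes. Of 175 Treg-list peaks in Th17n, 8 rose and 24 fell with DFMO.

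The second pattern is that DFMO effects in Th17n and iTreg were alike (r = 0.285). Abundance-trended offsets left r at 0.275, so counts concentrating in strong peaks are not the whole cause. Thinning every library to the smallest total left r at 0.243. The prediction for depth was written after the result. Its condition that every animal show the likeness was not met, since r was 0.024 in animal 1. In that animal the Th17n library with DFMO was deeper than that with vehicle (3077794 against 1020937 counts). Whether depth contributes is therefore left undecided. A shared response to the drug is consistent with r = 0.275 but could not be parted from any handling shared by the DFMO cultures.

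The third pattern is the gain at tRNA genes in Th17n (0.708). It was 0.64 with abundance-trended offsets and 0.546 without chromosome 13, where a large tRNA cluster lies (53 of 104 peaks rose, 0 fell). No list of 1000 matched random lists reached 0.71 (highest 0.178, or 0.205 from gene ends alone), so strength, width and place do not account for it. The tRNA medians were known before these predictions were written. Reads shared between near-identical tRNA copies and GC content were not tested and could still contribute to the remaining 0.546. A gain at genes read by RNA polymerase III is a possible biological explanation. Peaks at snRNA genes, here all outside chromosome 13, gained as well, so the gain was not confined to tRNA genes. Which polymerase reads the snRNA genes at these peaks was not checked, so they do not decide on this explanation. Protein-coding classes gained too. In Th17n 26 of 39 peaks at clustered histone genes and 17 of 81 at cytosolic ribosomal protein genes rose, and 0 fell. Of the histone peaks only 3 lie outside chromosome 13. A gain at genes of RNA polymerase III alone would not cover these protein-coding genes.

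Whether other groupings of the libraries give as many changes was tested with the 10 splits of each set of 6 libraries, too few for a share under 0.05. The other splits also mix libraries of both groups compared, which can raise the estimated spread. Low counts there therefore do not show what chance alone gives. In each comparison only 1 split, the real one, gave as many changed peaks. For DFMO in Th17n it gave 3841 and the highest other 0 (up to 2529 with an unadjusted p under 0.05), and for DFMO in iTreg 3742 and 651 (up to 6531 unadjusted). For the lineages it gave 19483 and 0 in vehicle (up to 2282 unadjusted) and 16280 and 0 under DFMO (up to 3317 unadjusted). In each case 3 other splits part as many pairs of animals, and all gave 0.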
